A study of Homo sapiens with 24 samples.

How the data were processed

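The values used here were as deposited by the authors, with gene-level and probe-set values for each of the 12 arrays. Per the labels, cells were seeded at least 24 h before treatment, and total RNA was purified with a column kit and checked for integrity. It was copied into single-stranded cDNA, labelled with biotin and hybridised to the Human Transcriptome Array 2.0. The authors scaled and summarised the arrays in Transcriptome Analysis Console 4.0 with its default settings, which gave the log2 values, and tested groups with an unpaired one-way analysis of variance and Benjamini-Hochberg correction. The background correction and summarisation methods within these settings are not given in the sources used here. The highest value was 19.93, and the array medians of the tested rows ran from 3.29 to 4.17, so that the values were used without a further transformation. The 2995 rows found in both tables were identical (largest difference 0).

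Of 70523 rows of the gene-level table, 2995 controls and probe sets were left out, and 67528 transcript-cluster rows were tested. Of these, 23781 carried 1 gene symbol, 1543 several and 42204 none, and 306 symbols were updated to current ones. Genes are named only from rows with exactly 1 symbol, and a gene with several rows is represented by the row with the highest mean. The probe-set table held 573909 exon and 339146 junction probe sets.

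Groups, comparisons, lists and settings were chosen before the data were examined, from the labels and the design text. The test was limma on the 6 group means with moderated variances and Benjamini-Hochberg adjustment over all rows of a comparison, called at an adjusted p under 0.05 without a fold threshold. The comparisons were isoginkgetin against DMSO in each line, the difference of these responses, the lines in DMSO, and DMSO against untreated in each line. Gene lists were written beforehand from general knowledge. There were 30 lists with 670 entries, of which 583 were measured in the gene-level table and 595 in the exon means, and they were tested with camera at a preset correlation of 0.01 and with an estimated correlation. Junction probe sets were compared with exon probe sets by the difference of their medians on each array, tested with an exact permutation within lines. Single probe sets, and their levels relative to the exons of their gene (640738 probe sets), were tested with the same limma fit.

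The replicates are biological replicates from independent experiments, according to the design text. That text does not say whether equal replicate numbers join arrays of 1 experiment, so this was read from correlations. After removal of group means, arrays of the same line with the same number correlated at 0.969 to 0.996 (6 pairs), and arrays of different lines with the same number at 0.0647 to 0.0914 (9 pairs). Equal numbers were therefore taken as a pairing within a line, and the fit with the replicate as a block is given wherever it changes a call. This was decided before its calls were compared. In the gene-level table the block gives 33783 rows a spread of 0, so that its calls there are not interpreted.

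The following was added after the data were seen. Exon means are the mean log2 value of all exon probe sets of a gene with at least 3 of them and 1 symbol (369758 probe sets, 18587 genes, median 16 per gene). Within-set tests compare isoginkgetin with DMSO with the set as a block, per line and over 4 or 3 sets, the latter also for single probe sets and their relative levels. The fits without the arrays labelled HCT116 replicate 1, the intensity trend, the random block and the comparison of that set with the others were also added. Adjusted p values of these added tests are from limma on 2 to 4 sets.

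Genes are named by a rule. CDKN1A, MDM2, ATF3, ATF4 and DDIT3 are given in every comparison; 1 further gene of this rule is not reported here. Beyond these, the 10 largest rises and the 10 largest falls among called genes are named in each line and between the lines, up to 5 of each in the other comparisons, and up to 4 members with the smallest adjusted p for a list that is described. Rises and falls needed both treated arrays beyond both DMSO arrays. In the added within-set tests, the responses of the sets had to share their sign instead, which is a weaker condition. The rest of the rule was repeated for the added tests. Pseudogenes, antisense genes and near-identical families are said to be uncertain.

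Alternatives covered quantile scaling, centring of arrays, the control group, the level filter, thresholds, leaving out each array and each set, and the plain unpaired test; their counts are in the robustness passage. The median level of an array changed by at most 0.019 log2 between isoginkgetin and DMSO, and the median and mean of every list called in the within-set tests kept their sign under quantile scaling and centring, except the median of the p53 targets in HCT116.

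The tests were first run on simulated data, drawn from the set means and within-set spread of the real values with changes planted in isoginkgetin arrays. At 2-, 4- and 8-fold, gene-level group means recovered 0, 1.49 and 19.7% in HCT116 and 0, 0 and 19.7% in the p53-null subline. Exon means with the block recovered 91.0, 100 and 100% and 94.0, 100 and 100%. For the difference these values were 82.1, 100 and 100%, and for the 4 sets pooled 98.5, 100 and 100%. With nothing changed, 0 genes were called. A list raised by 0.5 log2 had an adjusted p of 2.4e-43 with the preset and 0.00046 with an estimated correlation, and a junction shift of −0.2 log2 was measured as −0.2 (p = 0.00444, exact permutation). Each planted change was equal in all its sets, and noise was independent between genes. The junction shift was planted in every junction probe set, so that its recovery does not cover a change in only a part of them. Single genes were planted above the median level. Real responses differed between sets (CHAC1 −0.13 to 4.45 log2), and list members were correlated (ATF4 list 0.603 within 4 sets). These values therefore do not give the power for the real responses. Analyses used R 4.3.3, limma 3.58.1, data.table (version 1.17.8) and matplotlib 3.10.9. The number of arrays limits the precision of all values.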

Results

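Isoginkgetin is a plant biflavonoid described as an inhibitor of pre-mRNA splicing. Gene expression was measured after exposure to it in HCT116, a human colorectal carcinoma cell line, and in the p53-null subline of HCT116. Cells were left untreated, received the vehicle DMSO, or received 30 µM isoginkgetin for 8 h. Total RNA was then hybridised to the Affymetrix Human Transcriptome Array 2.0, which carries probe sets for exons and for exon junctions. Each of the 6 groups held 2 arrays, which came from independent experiments, and the 12 arrays gave a gene-level table and a probe-set table each. The 3 arrays of 1 cell line and 1 replicate number are called a set here, so that there were 4 sets. Arrays have no read depth, and the number of arrays limits the precision of every value.

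Markers of epithelial cells set the arrays labelled HCT116 replicate 1 apart from the other 3 sets. EPCAM, an adhesion molecule of epithelia, had a mean level of 4.62 (log2, mean over the gene's exon probe sets) in this set and of 12.00 to 12.17 in the others. The keratins KRT8, KRT18 and KRT19, which form the filaments of simple epithelia, lay at 5.78, 5.68 and 4.27, against 13.97 to 14.43, 12.17 to 12.64 and 11.49 to 12.07. CDH1, the adhesion protein of epithelial junctions, lay at 3.81 against 9.61 to 9.94. The tight junction genes CLDN4 and CLDN7 lay at 5.29 and 5.73, against 9.71 to 9.90 and 12.15 to 13.19. These 7 genes are the ones above 8 log2 in the other sets among 14 colon epithelium markers measured. The rest lay low in every set, such as VIL1 (4.78 against 3.34 to 3.67) and CDX2 (3.78 against 5.13 to 5.50). Genes that fibroblasts express lay higher in this set, with FBN1, a component of microfibrils, at 7.33 against 3.36 to 3.58, and THY1, a surface glycoprotein, at 7.79 against 3.61 to 3.67. The collagen genes COL1A1 and COL1A2, which fibroblasts express abundantly, lay at 4.8 and 4.67 in this set, close to the 4.00 to 4.14 and 3.63 to 3.79 of the others. VIM, which encodes an intermediate filament of mesenchymal cells and was chosen after its values were seen, lay at 12.56 against 3.10 to 3.67. Across the 67528 gene-level rows, the mean of this set correlated with the means of the other sets at a Pearson r of 0.912 to 0.919, against 0.986 to 0.988 among the other 3. Rows are not independent replicates. Counts of called genes are therefore also given without the arrays labelled HCT116 replicate 1.

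**Figure D1:**
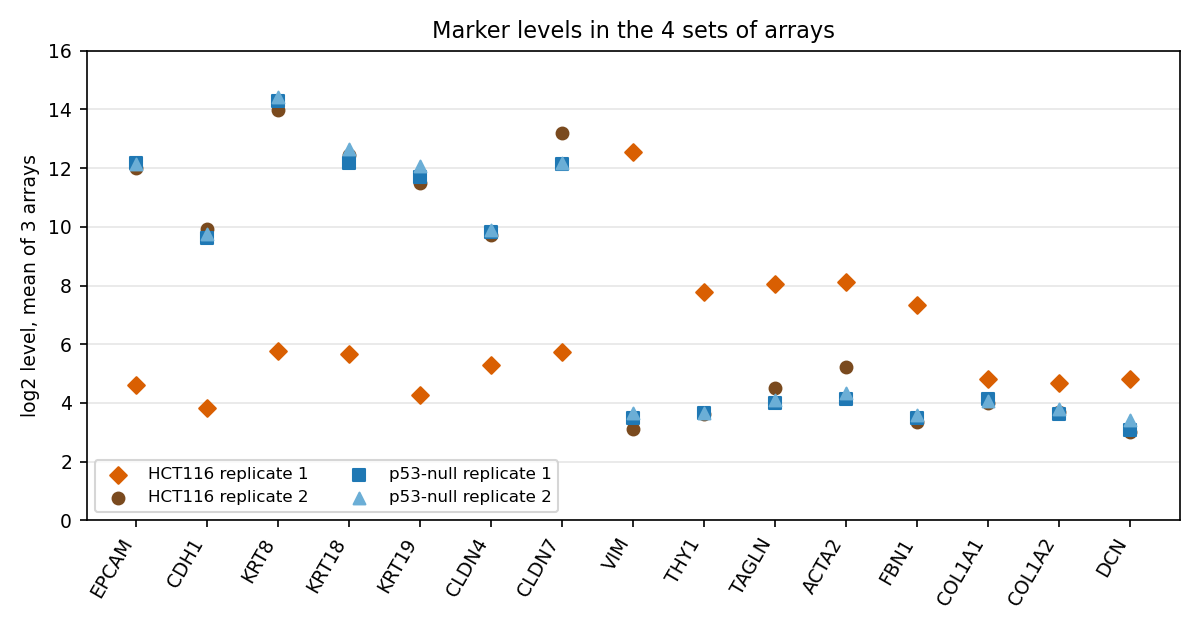
Mean log2 level of the 3 arrays of each set (vertical axis) for 7 colon epithelium markers, VIM and 7 fibroblast markers (horizontal axis), with 1 symbol per set. The 7 epithelial markers shown are those above 8 log2 in the other 3 sets, of 14 measured. In the arrays labelled HCT116 replicate 1 they lie between 3.81 and 5.78, and in the other 3 sets between 9.61 and 14.43.

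The first comparison asked which genes respond to isoginkgetin in the p53-null subline. In both p53-null sets, 2 genes of zinc transport changed in opposite directions. SLC30A1, which exports zinc from the cytosol, rose by 1.54 log2 (2.91-fold, SD 0.12, n = 2 sets, limma adjusted p = 0.045), and SLC39A10, a zinc importer of the plasma membrane, fell by 0.81 log2 (SD 0.16, n = 2 sets, limma adjusted p = 0.032). HSPA5, the main chaperone of the endoplasmic reticulum (ER), rose by 0.55 log2 (1.46-fold, SD 0.02, limma adjusted p = 0.032). DUSP4, a phosphatase of MAP kinases, rose by 1.13 log2 (2.20-fold, adjusted p = 0.048), and SCG2, a protein of secretory granules, by 0.99 log2 (adjusted p = 0.037). SLC33A1, which carries acetyl-CoA into the ER, rose by 0.77 log2 (adjusted p = 0.037), and CFAP263, AGPAT9 and GPCPD1 rose by 0.68, 0.55 and 0.54 log2. The rises of MT2A, a metallothionein (0.56 log2), and of ZSCAN12P1, a pseudogene (0.78 log2), are uncertain, because near-identical genes can bind the same probes. DACT1, an antagonist of WNT signalling (−0.60 log2), CTDSP2, a phosphatase (−0.54), and TCF7L2, a transcription factor of the WNT pathway (−0.48), fell as well. So did CLIP4 (−0.50), SRGAP1 (−0.47), STXBP4 (−0.45), ATXN1 (−0.44), TEAD2 (−0.43) and PTPN12 (−0.42), with adjusted p between 0.037 and 0.045.

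These values come from limma on the exon means with the replicate number as a block, a test added after the data were seen, which called 75 of 18587 genes in the p53-null sets (41 higher and 34 lower). The test chosen before the data were examined, which compares the gene-level means of the groups without a block, called 0 of 67528 rows, with 14 rows at an unadjusted p under 0.05. The plain unpaired test also called 0, and the block called 29 rows (16 higher and 13 lower). In the gene-level table, 74.2, 76.4, 82.4 and 83.2% of these rows were exactly equal on the 3 arrays of a set, so that drug effects were tested on the exon probe sets. Without the arrays labelled HCT116 replicate 1, which take part in the spread that this fit estimates, 447 genes were called (231 higher and 216 lower), and 385 of them had the same sign in HCT116 replicate 2. The largest rise in that fit was that of CHAC1, an enzyme that degrades glutathione, at 2.94 log2 (7.67-fold, SD 1.04, n = 2 sets, limma adjusted p = 0.018, against 0.33 with all arrays). DDIT4, an inhibitor of mTORC1, rose by 2.18 log2 there (adjusted p = 0.027), and SLC7A11, which imports cystine, by 1.94 log2 (adjusted p = 0.0081). SLC16A6, a transporter of the monocarboxylate family, rose by 2.02 log2 and NR4A2, a nuclear receptor induced by many stimuli, by 1.83. STC2, a secreted glycoprotein, rose by 1.38 log2, ULBP1, a ligand of natural killer cell receptors, by 1.34, SESN2, an inhibitor of mTORC1, by 1.28, and the uncertain MT1X by 1.26. The largest falls there were those of SOX4, a transcription factor (−0.97 log2, adjusted p = 0.025), NAV3 (−0.84), ELK3 (−0.81), SLC39A10 (−0.81), SPTSSB (−0.80), EMP1 (−0.77), ITGA2, a subunit of a collagen receptor (−0.74), MYEOV (−0.69), CAVIN1, a coat protein of caveolae (−0.67), and UCA1, a long noncoding RNA (−0.67). With all arrays and an intensity trend in the spread, 3 genes were called in place of 75, so that most of those calls were lost. The genes chosen in advance for every comparison did not pass the test with all arrays. CDKN1A, an inhibitor of cyclin-dependent kinases, had −0.14 log2 (adjusted p = 0.45), and MDM2, a ubiquitin ligase, 0.14 (0.35). The stress transcription factors ATF3, ATF4 and DDIT3 had 0.44 (0.19), 0.72 (0.23) and 0.73 (0.20). In the gene-level test they had 0 for CDKN1A, 0 for MDM2, 0.18, 0.76 and 0.52 log2, each with an adjusted p of 1.

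Among the 30 gene lists, those of the ER stress response and of metal handling rose in the p53-null sets. Of the 20 measured genes of the ER unfolded protein response, HSPA5 and HYOU1, another ER chaperone (0.51 log2, adjusted p = 0.037), rose over all genes tested. When adjusted over the list alone 14 rose (median 0.28 log2, camera adjusted p = 3.1e-15 with a preset correlation, and adjusted p = 0.025 with an estimated correlation). Of the 9 metallothioneins and zinc genes 3 rose, SLC30A1, MT2A and MT1E. In all 6 rose when adjusted over the list alone (median 0.48 log2, camera adjusted p = 7.5e-09, and adjusted p = 0.046 with an estimated correlation). The targets of ATF4, the transcription factor of the integrated stress response, had a median of 0.30 log2. Over all genes 0 of 33 were called, and 13 rose when adjusted over the list alone (camera adjusted p = 2.5e-09, but adjusted p = 0.77 with an estimated correlation). Of 19 aminoacyl-tRNA synthetases, which load tRNAs, YARS1 rose (0.36 log2, adjusted p = 0.037). There were 7 when adjusted over the list alone (camera adjusted p = 5.1e-07, but adjusted p = 0.11 with an estimated correlation). The targets of AHR, a receptor of xenobiotics, also passed camera upward with 0 of 5 genes called (adjusted p = 0.046, but adjusted p = 0.77 with an estimated correlation). The cholesterol synthesis and G2/M lists passed it downward with 0 genes called over all genes (adjusted p = 0.014 and 0.00096, but adjusted p = 0.99 and 0.69 with an estimated correlation). Of the cholesterol genes 1 fell when adjusted over the list alone. Of 32 core spliceosome genes 1 rose, PRPF4, a protein of the U4/U6 particle (0.41 log2, adjusted p = 0.037), and the list did not pass (camera adjusted p = 0.92).

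On the gene-level rows, 9 lists passed camera in the p53-null subline (8 up and 1 down), and 4 passed with an estimated correlation. The metallothioneins were 1 of these (mean 0.70 log2, adjusted p = 5.9e-74, and adjusted p = 0.00029 with an estimated correlation). So were the ATF4 list (mean 0.48 log2, adjusted p = 1.3e-82, and adjusted p = 0.0071 with an estimated correlation) and the ER unfolded protein response (mean 0.25 log2, adjusted p = 1.3e-71, and adjusted p = 0.0071 with an estimated correlation). The last were the targets of NRF2, the regulator of antioxidant genes (mean 0.07 log2, median 0, adjusted p = 0.00083, and adjusted p = 0.045 with an estimated correlation). The first 3 passed upward with every single array left out. The NRF2 list did not pass without DMSO 1 (adjusted p = 0.34), DMSO 2 (0.37), isoginkgetin 1 (0.42) or isoginkgetin 2 (0.26) of the p53-null subline, nor without the arrays labelled HCT116 replicate 1 (0.75), nor with the block (0.81). No member of any list was called on its own in this test, nor when adjusted over the list alone. Camera compares a list with all other rows, of which 87.1 and 86.7% were exactly equal between isoginkgetin and DMSO in the p53-null sets. A few members with a difference can thus give a very small adjusted p. The estimated correlation comes from the fit without a block, where the difference between sets enters. The size of these adjusted p values is therefore not interpreted. The number of lists moved to 14 (3 up and 11 down) without p53-null DMSO 1 and to 14 (3 up and 11 down) without p53-null isoginkgetin 2. It was 7 (4 up and 3 down) with the block, 13 (13 up and 0 down) without p53-null DMSO 2 and 13 (13 up and 0 down) without p53-null isoginkgetin 1, and 6 (6 up and 0 down) without the arrays labelled HCT116 replicate 1.

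The same comparison was made in the 2 sets labelled HCT116, the parental line, although replicate 1 of them was low in epithelial markers. In both sets labelled HCT116, metallothionein genes, whose products bind zinc and copper, rose: MT1F by 2.29 log2 (4.89-fold, SD 1.13, n = 2 sets, limma adjusted p = 0.022), MT1X by 1.27 (2.41-fold, adjusted p = 0.029), MT1M by 1.06 (adjusted p = 0.045), MT1H by 0.77 (0.032), MT2A by 0.70 (0.012) and the pseudogene MT1L by 0.65 (0.027). These genes are nearly identical in sequence, so that each single value is uncertain. SLC39A10 fell by 0.72 log2 (SD 0.04, n = 2 sets, limma adjusted p = 0.011). DDIT3, a transcription factor of prolonged ER stress, rose by 1.23 log2 (2.35-fold, SD 0.61, limma adjusted p = 0.029), with 0.80 in the arrays labelled HCT116 replicate 1 and 1.67 in replicate 2. LY6G5B, IQCN and TMEM116 rose by 0.78, 0.72 and 0.68 log2. The largest fall was that of TEAD4, a transcription factor of the Hippo pathway (−1.07 log2, SD 0.35, adjusted p = 0.017). It was followed by PMM2, an enzyme of protein glycosylation (−0.85), CDR2L (−0.83), SLC25A32, a mitochondrial folate carrier (−0.79), TSR2 (−0.74), ELK3, a transcription factor of the ETS family (−0.72), CRLF3 (−0.69), EHD4 (−0.69) and YDJC (−0.68), with adjusted p between 0.017 and 0.049.

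In this added within-set test, limma called 698 of 18587 genes in the sets labelled HCT116 (129 higher and 569 lower), with 5 at 2-fold or more. The gene-level test chosen beforehand called 0 rows, with 34 at an unadjusted p under 0.05. The plain unpaired test called 0, and the block called 175 rows (76 higher and 99 lower). Without the arrays labelled HCT116 replicate 1, where the lone HCT116 set is assumed to vary like the p53-null sets, the count was 2580 (898 higher and 1682 lower). CDKN1A had 0 log2 (adjusted p = 1), MDM2 0.07 (0.46), ATF3 0.29 (0.18) and ATF4 0.45 (0.23). In the gene-level test CDKN1A had −0.03 log2, MDM2 0, ATF3 0.19, ATF4 0.50 and DDIT3 1.06 (SE 0.49), each with an adjusted p of 1.

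Of the gene lists, the metallothioneins rose within the sets labelled HCT116, with 6 of 9 genes over all genes tested and 9 when adjusted over the list alone (median 0.77 log2, camera adjusted p = 3.9e-08, but adjusted p = 0.097 with an estimated correlation). The ribosome biogenesis list fell, with RRN3, a factor of RNA polymerase I (−0.27 log2, adjusted p = 0.030), WDR43 (−0.19, 0.043) and MYBBP1A (−0.47, 0.045) among 21 genes. In all 11 fell when adjusted over the list alone (median −0.21 log2, camera adjusted p = 2.9e-06, but adjusted p = 0.24 with an estimated correlation). The DNA replication list fell, with SLBP, which binds histone mRNA (−0.37 log2, adjusted p = 0.022), CHAF1B, a subunit of a histone chaperone (−0.23, 0.028), and GINS2, a subunit of the replicative helicase (−0.39, 0.042), among 27 genes. When adjusted over the list alone 10 fell (camera adjusted p = 1e-05, but adjusted p = 0.49 with an estimated correlation). The p53 targets fell with 2 of 29 genes, AEN, a nuclease (−0.61 log2, adjusted p = 0.042), and XPC, a DNA damage sensor (−0.27, 0.043). In all 4 fell when adjusted over the list alone (median −0.04 log2, and 0.01 with quantile scaling; camera adjusted p = 0.038, but adjusted p = 0.25 with an estimated correlation). Of the ATF4 list 1 of 33 genes rose, DDIT3, also when adjusted over the list alone (camera adjusted p = 0.00052, but adjusted p = 0.63 with an estimated correlation). Of the ER unfolded protein response 1 of 20 rose, HSPA5 at 0.34 log2 (adjusted p = 0.017), also when adjusted over the list alone (camera adjusted p = 0.0041, but adjusted p = 0.24 with an estimated correlation). Of 9 replication-dependent histone genes, H1-4 rose (0.32 log2, adjusted p = 0.027). In all 2 rose when adjusted over the list alone (camera adjusted p = 0.012, but adjusted p = 0.25 with an estimated correlation). Histone genes are a near-identical family, and their values are uncertain.

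On the gene-level rows, 13 lists passed camera in HCT116 (4 up and 9 down) and 1 with an estimated correlation. This was the metallothionein list (mean 0.90 log2, adjusted p = 2.5e-41, and adjusted p = 0.0016 with an estimated correlation), with 0 members called. That list did not pass without HCT116 DMSO 1 (adjusted p = 0.31) or isoginkgetin 2 (0.61). In the sets labelled HCT116, 77.9 and 79.0% of the rows were exactly equal between isoginkgetin and DMSO. The size of these adjusted p values is therefore not interpreted. The number of lists moved to 22 (2 up and 20 down) without DMSO 1, to 24 (23 up and 1 down) without isoginkgetin 1, to 23 (22 up and 1 down) without DMSO 2 and to 19 (0 up and 19 down) without isoginkgetin 2. Without a block, leaving out 1 array of a pair brings the difference between the sets into the comparison. With the block 9 lists passed (4 up and 5 down). The number was 13 (7 up and 6 down) without the arrays labelled HCT116 replicate 1.

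To ask what both lines shared, isoginkgetin was compared with DMSO within all 4 sets together, a test added after the data were seen. SLC39A10, SLC30A1 and MT1X, which act in zinc handling, moved the same way in all 4 sets. SLC39A10 fell by 0.77 log2 (SD 0.11, n = 4 sets, limma adjusted p = 0.00038), with falls of 0.69 to 0.92 log2 in single sets in the plot of named genes. MT1X rose by 1.26 log2 (2.40-fold, SD 0.41, n = 4 sets, adjusted p = 0.0050) and MT1F, like MT1X uncertain, by 1.66 (3.15-fold, adjusted p = 0.033). SLC30A1 rose by 1.17 log2 (2.26-fold, SD 0.56, adjusted p = 0.021). SLC16A6 rose by 1.80 log2 (3.49-fold, SD 1.12, adjusted p = 0.034), with 0.27 in the arrays labelled HCT116 replicate 1 and 1.86 to 2.92 in the other sets. NR4A2 (1.43 log2, adjusted p = 0.041), ULBP1 (1.31, 0.047), STC2 (1.12, 0.024), SESN2 (1.1, 0.040), DDIT3 (0.98, 0.020) and CREB3L2, a transcription factor of the ER membrane (0.96, 0.042), also rose. Beside SLC39A10, the largest falls were those of EMP1, a membrane protein (−0.79 log2, adjusted p = 0.043), ELK3 (−0.76, 0.0080), NAV3 (−0.69, 0.025), CAVIN1 (−0.66, 0.017), RIGI, a sensor of viral RNA (−0.63, 0.0098), SMURF2, a ubiquitin ligase (−0.56, 0.021), VEZF1 (−0.54, 0.025), RIC1 (−0.53, 0.0061) and SRGAP1 (−0.52, 0.0048). ATF3 rose by 0.37 log2 (adjusted p = 0.044), whereas CDKN1A (−0.07 log2, adjusted p = 0.40), MDM2 (0.10, 0.18) and ATF4 (0.58, 0.062) did not pass.

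**Figure D2:**
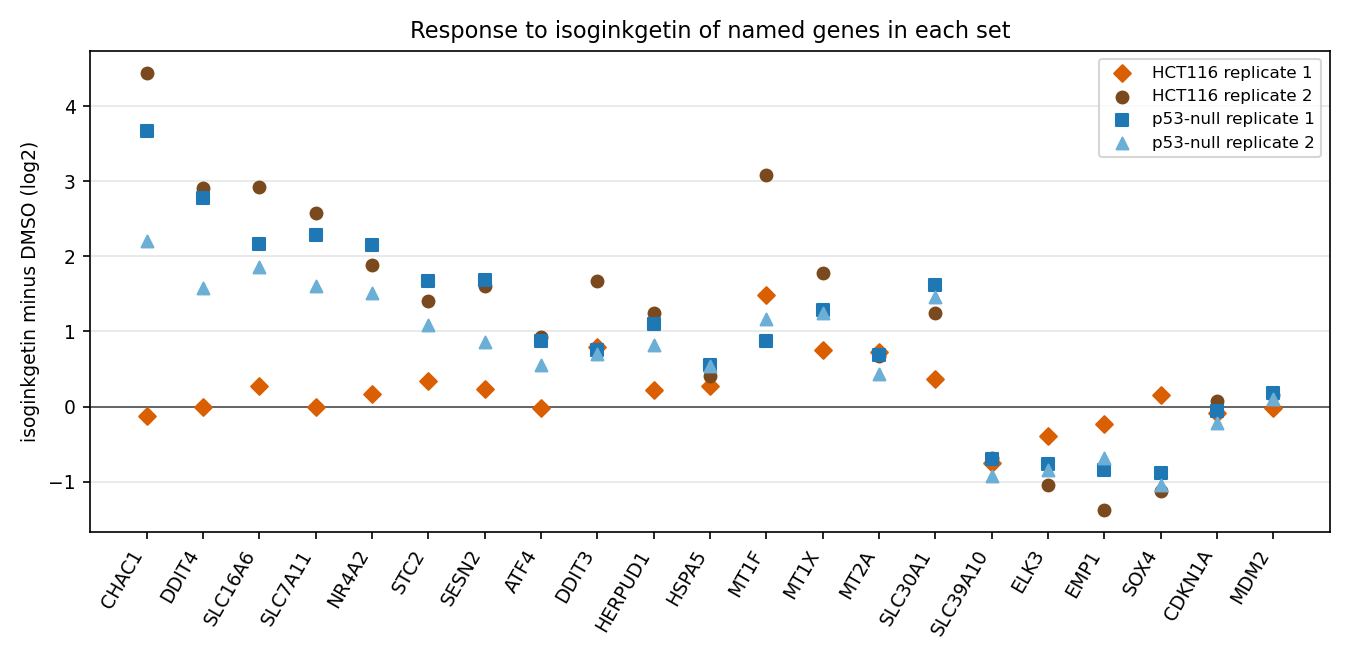
Isoginkgetin minus DMSO (log2, vertical axis) of named genes (horizontal axis), with 1 symbol for each of the 4 sets. SLC39A10 lies between −0.92 and −0.69 in all sets, whereas CHAC1 lies at −0.13 in the arrays labelled HCT116 replicate 1 and between 2.21 and 4.45 in the others.

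The test within the 4 sets called 574 of 18587 genes (207 higher and 367 lower), of which 572 had the same sign in every set, and 9 were 2-fold or more higher. The count was 476 without the arrays labelled HCT116 replicate 1, 88 without HCT116 replicate 2, 1 without p53-null replicate 1 and 25 without p53-null replicate 2. SLC39A10 was called in each of these, with adjusted p of 0.0036, 0.0055, 0.035 and 0.0067. MT1X lost its call without p53-null replicate 1 (0.11) and without p53-null replicate 2 (0.057). SLC30A1 was kept only without the arrays labelled HCT116 replicate 1 (0.00086), with 0.089, 0.15 and 0.10 in the other fits. The median of the exon probe sets in place of their mean gave 20 calls, and the fit without a block gave 0, with the same genes tested.

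Without the arrays labelled HCT116 replicate 1, the largest rises in the other 3 sets were those of CHAC1, DDIT4 and SLC16A6. CHAC1 rose by 3.44 log2 (10.9-fold, SD 1.14, n = 3 sets, limma adjusted p = 0.012), DDIT4 by 2.42 (5.36-fold, SD 0.73, adjusted p = 0.0092) and SLC7A11 by 2.16 (4.45-fold, SD 0.50, adjusted p = 0.0042). The arrays labelled HCT116 replicate 1 had −0.13, 0 and −0.01 log2 for these genes, and over all 4 sets their limma adjusted p were 0.075, 0.060 and 0.050. SLC7A11 (1.61 log2 over 4 sets) thus lay at the threshold. It is not among the rises named over 4 sets, for which all sets had to share their sign. SLC16A6 rose by 2.32 log2, NR4A2 by 1.85, ULBP1 by 1.65, SLC30A1 by 1.44, the uncertain MT1X by 1.43, and SESN2 and STC2 by 1.39 each, with adjusted p between 0.00086 and 0.021. ATF4 rose by 0.79 log2 (adjusted p = 0.0063), ATF3 by 0.47 (0.0064) and DDIT3 by 1.04 (0.038), whereas CDKN1A had −0.07 log2 (0.55) and MDM2 0.15 (0.13). SOX4 fell by 1.02 log2 (SD 0.12, n = 3 sets, adjusted p = 0.0070) and had 0.15 in the arrays labelled HCT116 replicate 1. EMP1 (−0.98 log2), ELK3 (−0.89), NAV3 (−0.87), CAVIN1 (−0.79), SLC39A10 (−0.77), ZNF827 (−0.71), SPTSSB (−0.69), SMURF2 (−0.67) and ITGA2 (−0.65) also fell. Of the 476 genes called in the 3 sets, 150 of the 209 that rose were also higher in the arrays labelled HCT116 replicate 1 and 205 of the 267 that fell were also lower there, and 276 were among the calls within 4 sets, all with the same sign.

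Within the 4 sets, 10 lists passed camera with the preset correlation (5 up and 5 down), and 0 with an estimated correlation. Over the 3 sets 8 passed (5 up and 3 down), and 0 with an estimated correlation. The ATF4 list rose with 8 of 33 genes over all genes and 19 when adjusted over the list alone (median 0.28 log2, camera adjusted p = 1.6e-09, but adjusted p = 0.46 with an estimated correlation). Among them were DDIT3, STC2, JDP2 (0.28 log2, adjusted p = 0.025) and CEBPG (0.29, 0.032). Over 3 sets it rose with 14 genes and 24 when adjusted over the list alone (median 0.34 log2, camera adjusted p = 3.7e-20, but adjusted p = 0.35 with an estimated correlation). Its median in the arrays labelled HCT116 replicate 1 was −0.01 log2. The ER unfolded protein response rose with 5 of 20 genes and 13 when adjusted over the list alone (median 0.16 log2, camera adjusted p = 1.6e-09, but adjusted p = 0.31 with an estimated correlation). Among them were HSPA5 (0.44 log2, adjusted p = 0.0050), SEL1L (0.33, 0.027), SEC24D (0.48, 0.030) and HERPUD1 (0.85, 0.032), which serve protein quality control or transport at the ER. Over 3 sets it rose with 7 genes and 13 when adjusted over the list alone (camera adjusted p = 3.7e-11, but adjusted p = 0.16 with an estimated correlation). The metallothioneins and zinc genes rose with 6 of 9 genes and 9 when adjusted over the list alone (median 0.63 log2, camera adjusted p = 3.7e-10, but adjusted p = 0.081 with an estimated correlation). Among them were MT1E (0.55 log2, adjusted p = 0.0036) and MT2A (0.63, 0.0048). Over 3 sets they rose with 5 genes and 9 when adjusted over the list alone (camera adjusted p = 2.8e-12, but adjusted p = 0.26 with an estimated correlation). Of 19 aminoacyl-tRNA synthetases 1 rose, WARS1 at 0.36 log2 (adjusted p = 0.049). When adjusted over the list alone 10 rose (camera adjusted p = 0.00082, but adjusted p = 0.46 with an estimated correlation). Over 3 sets 7 rose, among them CARS1 (0.49 log2) and AARS1 (0.60), and 10 when adjusted over the list alone (camera adjusted p = 3e-06, but adjusted p = 0.35 with an estimated correlation). Of 5 AHR targets TIPARP, an ADP-ribosyltransferase, rose (0.36 log2, adjusted p = 0.029), and 3 when adjusted over the list alone (camera adjusted p = 0.0056, but adjusted p = 0.42 with an estimated correlation). Over 3 sets 0 were called and 4 rose when adjusted over the list alone (camera adjusted p = 0.0017, but adjusted p = 0.45 with an estimated correlation).

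Of 27 DNA replication genes CHAF1B (−0.23 log2, adjusted p = 0.0053) and SLBP (−0.27, 0.030) fell, and 3 when adjusted over the list alone (median −0.08 log2, camera adjusted p = 3.6e-05, but adjusted p = 0.46 with an estimated correlation). Over 3 sets CHAF1B fell, also when adjusted over the list alone (1 of 27, camera adjusted p = 4.8e-05, but adjusted p = 0.62 with an estimated correlation). Of 28 G2/M genes AURKB, a mitotic kinase, fell (−0.19 log2, adjusted p = 0.045), and 2 when adjusted over the list alone (camera adjusted p = 0.0056, but adjusted p = 0.42 with an estimated correlation). Over 3 sets NUSAP1, a protein of the spindle, fell (−0.19 log2, adjusted p = 0.045), but it had 0.46 log2 in the arrays labelled HCT116 replicate 1. When adjusted over the list alone 1 gene fell over the 3 sets (camera adjusted p = 0.0055, but adjusted p = 0.46 with an estimated correlation). Of 20 genes of cholesterol synthesis 0 were called within 4 sets, also when adjusted over the list alone (camera adjusted p = 0.024, but adjusted p = 0.68 with an estimated correlation). The list did not pass without HCT116 replicate 2 (adjusted p = 0.82), without p53-null replicate 1 (0.057) or without p53-null replicate 2 (0.12). Over 3 sets 4 of them fell, IDI1 (−0.29 log2, adjusted p = 0.010), MSMO1 (−0.23, 0.029), FDFT1 (−0.19, 0.036) and INSIG1, which retains the regulator of the pathway in the ER (−0.43, 0.046). When adjusted over the list alone 10 fell (median −0.18 log2, camera adjusted p = 2.4e-07, but adjusted p = 0.35 with an estimated correlation). In the arrays labelled HCT116 replicate 1 the list median was 0.13 log2. IDI1, MSMO1, FDFT1 and INSIG1 had 0.01, 0.23, 0.14 and −0.03 log2 there. The p53 targets passed downward within 4 sets with 1 of 29 genes, PLK2, a stress-induced kinase (−0.50 log2, adjusted p = 0.019; 1 gene when adjusted over the list alone, camera adjusted p = 0.028, but adjusted p = 0.40 with an estimated correlation). They did not pass without the arrays labelled HCT116 replicate 1 (adjusted p = 0.085) or without HCT116 replicate 2 (0.050). The ribosome biogenesis list passed downward with 0 of 21 genes called, also when adjusted over the list alone (camera adjusted p = 0.030, but adjusted p = 0.68 with an estimated correlation). It did not pass without the arrays labelled HCT116 replicate 1 (0.25) or without HCT116 replicate 2 (0.55). Splicing factors themselves did not pass as a group over the sets, with 0 of 32 core spliceosome genes and 0 of 24 SR proteins, hnRNPs and splicing kinases called by limma within 4 sets or 3 sets, also when adjusted over the list alone (camera adjusted p = 0.47 and 0.24 over 4 sets, 0.44 and 0.18 over 3). The member with the smallest adjusted p within 4 sets was SNRNP70, a protein of the U1 particle, at −0.22 log2 (adjusted p = 0.10). The SR and hnRNP list passed downward on the gene-level rows in HCT116 (mean −0.05 log2, camera adjusted p = 0.028, but adjusted p = 0.63 with an estimated correlation). Its member SRSF6 fell there on the exon means (−0.26 log2, adjusted p = 0.022). In the difference of the responses without the arrays labelled HCT116 replicate 1 the SR and hnRNP list was higher in the p53-null response (median 0.12 log2, camera adjusted p = 0.0076, but adjusted p = 0.68 with an estimated correlation). Of the core spliceosome 7 genes were higher and 1 lower in that test, among them PRPF4 (0.68 log2, adjusted p = 0.013) and SNRPA (−0.50, 0.017), without a call for the list (camera adjusted p = 0.24).

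**Figure D3:**
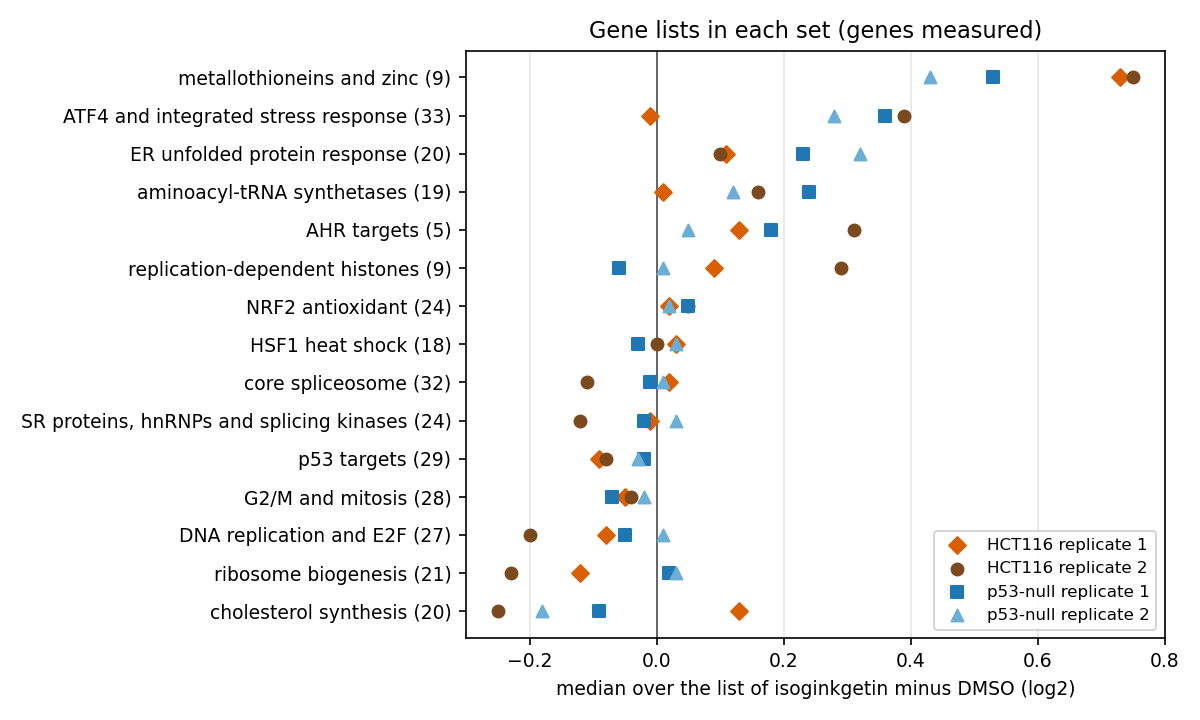
Median over each gene list of isoginkgetin minus DMSO (log2, horizontal axis) for 15 of the lists (vertical axis, with the number of genes measured), with 1 symbol for each of the 4 sets. The metallothionein list lies between 0.43 and 0.75 in all sets, and the ATF4 list at −0.01 in the arrays labelled HCT116 replicate 1 and between 0.28 and 0.39 in the others.

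Whether the response differs between the lines was tested as the difference of the isoginkgetin responses, p53-null minus HCT116. With DMSO as control, 0 genes differed over all arrays in either test. On the gene-level rows limma called 0, with 3 rows at an unadjusted p under 0.05, and the block called 122 rows (72 higher and 50 lower). On the exon means with the block limma called 0 genes, with 2430 at an unadjusted p under 0.05 and a smallest adjusted p of 0.12. A split of the vehicle arrays, given under the flagged results, equals this difference with DMSO and untreated arrays together as control. It called 162 genes. CDKN1A differed by −0.14 log2 (adjusted p = 0.53), MDM2 by 0.08 (0.69), ATF3 by 0.15 (0.73), ATF4 by 0.26 (0.73), DDIT3 by −0.50 (0.49) and SLC39A10 by −0.09 (0.67). In the gene-level test CDKN1A, MDM2, ATF3, ATF4 and DDIT3 differed by 0.03, 0, −0.01, 0.26 and −0.54 log2, each with an adjusted p of 1. Without the arrays labelled HCT116 replicate 1, 1104 genes differed (734 higher and 370 lower in the p53-null response), a count in which 1 HCT116 set is assumed to vary like the p53-null sets. The genes with the largest differences there followed the lone HCT116 set. CHMP1A, a protein of membrane scission, had −1.56 log2 in HCT116 replicate 2 and −0.17 in the arrays labelled HCT116 replicate 1 (difference 1.38, adjusted p = 0.0040). AP3M2, a subunit of a vesicle adaptor, had −1.30 and −0.13 (difference 1.33), NPM3, a nucleolar chaperone, −1.05 and −0.06 (1.24), SNX12 −1.34 and −0.35 (1.23) and TSR3 −1.08 and −0.07 (1.2). In the other direction ATP5F1D, a subunit of ATP synthase, had 1.78 and −0.08 (difference −1.94), ARL2, a small GTPase, 1.72 and 0.05 (−1.70), LINC00273 1.25 and −0.02 (−1.58) and NPW, a neuropeptide, 1.39 and 0.07 (−1.50). The uncertain MT1F had 3.09 and 1.49 (−2.07), and these adjusted p lay between 0.0040 and 0.0096.

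Among the gene lists, 7 differed on the gene-level rows (6 higher and 1 lower in the p53-null response) and 0 with an estimated correlation. Among these were the ribosome biogenesis list (mean 0.13 log2, camera adjusted p = 1.7e-10, but adjusted p = 0.33 with an estimated correlation) and the metallothioneins (mean −0.20 log2, adjusted p = 0.0088, but adjusted p = 0.58 with an estimated correlation), with 0 members called, also when adjusted over the list alone. Most rows were exactly equal between isoginkgetin and DMSO within a set, which limits these values as well. With the block 10 lists differed (9 up and 1 down). The number also moved with single arrays left out of the fit without a block, where the difference between sets enters. In HCT116 it was 23 (22 up and 1 down) without DMSO 1, 22 (1 up and 21 down) without isoginkgetin 1, 20 (2 up and 18 down) without DMSO 2 and 23 (23 up and 0 down) without isoginkgetin 2. In the p53-null subline it was 7 (0 up and 7 down) without DMSO 1, 12 (12 up and 0 down) without isoginkgetin 1, 13 (13 up and 0 down) without DMSO 2 and 8 (2 up and 6 down) without isoginkgetin 2. It was 5 (3 up and 2 down) without the arrays labelled HCT116 replicate 1. On the exon means without the arrays labelled HCT116 replicate 1, 9 lists differed and 0 with an estimated correlation. The ribosome biogenesis list was higher in the p53-null response with 8 of 21 genes and 14 when adjusted over the list alone, among them BYSL (0.73 log2, adjusted p = 0.0073) and NOLC1 (0.63, 0.013; list median 0.27, camera adjusted p = 1e-06, but adjusted p = 0.68 with an estimated correlation). The ATF4 list was lower with 4 genes, among them NUPR1, a stress-induced chromatin protein (−1.17 log2, adjusted p = 0.0073), and DDIT3 (−0.93, 0.014), and higher with 1, PPP1R15A (0.45, 0.031; camera adjusted p = 0.00011, but adjusted p = 0.68 with an estimated correlation).

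The lines were compared in DMSO to see how they differed before the drug. NRIP1, a corepressor of nuclear receptors, lay at 10.51 and 10.37 log2 in the 2 arrays labelled HCT116 and at 3.29 and 3.39 in the p53-null arrays (difference −7.10, SE 0.22, limma adjusted p = 1.9e-05). ARAF, a kinase of the RAF family, differed by −4.79 log2 (SE 0.30, adjusted p = 0.0015), and NOLC1, a nucleolar phosphoprotein, by −3.04 (SE 0.26, adjusted p = 0.018). TM4SF18, a membrane protein, was higher by 5.91 log2 (SE 0.32, adjusted p = 0.00069). These genes kept their direction in the arrays of both replicates. The designed limma test called 6 of 67528 rows (1 higher and 5 lower), with 2940 at an unadjusted p under 0.05, and 2 of the 6 rows carried no single symbol and are not named. Quantile scaling gave 388 calls, with 233 higher and 155 lower, so that the balance of directions depended on the scaling. The plain unpaired test called 0. The block called 59936 rows (12649 higher and 47287 lower), but it measures the lines against the spread within sets, so that these calls are not interpreted. NOLC1 lost its call without any 1 of the 4 arrays, and ARAF without p53-null DMSO 2 (adjusted p = 0.052). CDKN1A differed by −0.81 log2 (adjusted p = 0.82), MDM2 by −1.12, ATF3 by −0.48, ATF4 by −0.76 and DDIT3 by 0.26, and none of them passed.

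Without the arrays labelled HCT116 replicate 1, 142 of 18587 genes differed on the exon means (42 higher and 100 lower in the p53-null subline), with the lone HCT116 array assumed to vary like the other groups. This fit takes the arrays of a set as independent, although they are close to equal, which can make its adjusted p too small. Over all arrays the exon means gave 7 calls, and 3 with the set as a random block (correlation 0.981). NRIP1 (−5.56 log2, adjusted p = 0.0035), ARAF (−3.54, 0.011), NOLC1 (−2.74, 0.025) and TM4SF18 (4.2, 0.029) were among the 142. ZBED2, a transcription factor, was higher by 4.94 log2, WNT16, a secreted WNT ligand, by 4.70 and ZNF134 by 3.78. Over all arrays these values were 5.58, 5.69 and 1.04. For ZNF134 the array labelled HCT116 replicate 1 lay at 9.53, above the p53-null arrays (7.78 and 7.87). SLC2A3, a glucose transporter (2.63), and PDE4B, a cAMP phosphodiesterase (2.60), were higher as well, as were CAMK2D (2.48), NECTIN3 (2.27), CD109 (2.12) and FGF9 (2.06). Over all arrays SLC2A3 turned to −0.2 log2, because the array labelled HCT116 replicate 1 lay at 9.86, above the p53-null arrays (6.88 and 6.76). DPP4, a serine peptidase of the cell surface, differed by −5.25 log2, CYP4F11, a cytochrome P450, by −4.86, and PRKAA2, a catalytic subunit of AMP-activated kinase, by −4.76. The array labelled HCT116 replicate 1 lay at 4.1, 4.9 and 4.07 for these genes. Over all arrays their differences were −2.72, −2.04 and −2.56. Also lower were PROM1, a membrane glycoprotein (−4.60), ADGRF1 (−4.27), CAPN6 (−3.80), RGS2 (−3.72) and CASP4, an inflammatory caspase (−3.16). Over all arrays these values were −2.56, −1.13, −2.66, −5.67 and −2.39. MDM2 differed by −1.15 log2 (adjusted p = 0.043), whereas CDKN1A (−1.09, 0.27), ATF3 (−0.80, 0.087), ATF4 (−0.03, 0.94) and DDIT3 (0.59, 0.30) did not pass.

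The p53 targets lay lower in the p53-null subline. On the gene-level rows the list of 27 measured genes had a median of −1.18 log2, with 0 called over all rows, and 8 lower and 1 higher when adjusted over the list alone (camera adjusted p = 6.5e-09, but adjusted p = 0.34 with an estimated correlation). Without the arrays labelled HCT116 replicate 1, 24 of 29 targets lay lower (median −0.83 log2), compared with 45.6% of all genes. Most members of several other lists lay lower in that fit as well, with 25 of 27 DNA replication genes, 19 of 22 interferon genes, 17 of 20 cholesterol genes, 24 of 33 ATF4 genes and 24 of 32 core spliceosome genes. Other lists lay mostly higher, with 6 of 28 G2/M genes, 8 of 27 cytosolic ribosomal proteins, 12 of 31 immediate early genes and 4 of 14 WNT targets lower. Over all genes MDM2 was lower and PLK2 higher by 1.75 log2 (adjusted p = 0.024), and 9 were lower and 2 higher when adjusted over the list alone (camera adjusted p = 5.3e-07, but adjusted p = 0.96 with an estimated correlation). In all 8 lists passed camera between the lines (4 up and 4 down) and 0 with an estimated correlation. The others lower in the subline were the ATF4 (median −1.43 log2, adjusted p = 1.7e-05), interferon (−0.79, 0.00014) and cholesterol lists (−0.92, 0.00033), with adjusted p = 0.66, 0.57 and 0.75 with an estimated correlation. Those higher were the immediate early (mean 0.78 log2, adjusted p = 2.9e-06), G2/M (2.9e-06), colon epithelium (mean 1.83, median 0.05, 0.0050) and blood and endothelium lists (mean 0.09, median −0.06, 0.044), with adjusted p = 0.28, 0.28, 0.34 and 0.66 with an estimated correlation. The arrays labelled HCT116 replicate 1, low in epithelial markers, enter these values. Without them 15 lists passed (0 up and 15 down). With the block 2 passed (2 up and 0 down). Leaving out single arrays gave 16 lists (0 up and 16 down) without HCT116 DMSO 1, 17 (14 up and 3 down) without HCT116 DMSO 2 and 15 (5 up and 10 down) without p53-null DMSO 2.

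The vehicle was compared with untreated cells as the background of the drug comparisons. DMSO changed 0 rows in either line in the designed limma test, with 1 row in HCT116 and 15 in the p53-null subline at an unadjusted p under 0.05. The plain unpaired test called 0, and the block 8 rows (4 higher and 4 lower) and 4 rows (4 higher and 0 lower). Within the 4 sets together limma on the exon means called 0 genes, with 424 at an unadjusted p under 0.05, and 0 without the arrays labelled HCT116 replicate 1, with 564. CDKN1A, MDM2, ATF3, ATF4 and DDIT3 differed between DMSO and untreated arrays by −0.03 to 0 log2 in the gene-level test. Within single sets, 22 genes were 2-fold or more higher and 6 lower with isoginkgetin in the arrays labelled HCT116 replicate 1, against 0 with DMSO alone. The counts were 39 and 28 against 4 in HCT116 replicate 2, 20 and 0 against 3 in p53-null replicate 1, and 10 and 1 against 0 in p53-null replicate 2.

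Because isoginkgetin is described as a splicing inhibitor, probe sets that span exon junctions, which bind spliced RNA, were compared with probe sets inside exons. The median of 339146 junction probe sets relative to that of 573909 exon probe sets differed between isoginkgetin and control arrays by 0.00388 log2 (p = 0.862, exact permutation test within cell lines, two-sided, smallest possible p 0.00444). The value was 0.00264 in HCT116 and 0.00511 in the p53-null subline. With deviations taken within sets it was −0.0011 (p = 0.815, exact permutation test, 81 assignments). Leaving out single arrays, the first value ran from −0.0215 without p53-null isoginkgetin 2 to 0.0288 without p53-null isoginkgetin 1. With only rows above the median level of their class it was 0.023 (p = 0.351, exact permutation test within cell lines). That value was 0.0357 in HCT116 and 0.0103 in the p53-null subline. A median over all junctions, many of them in genes with low levels, can miss a change in a part of them. In HCT116 replicate 1 and 2 and p53-null replicate 1 and 2, 8.41, 11.5, 8.57 and 5.68% of junction probe sets lay over 2-fold apart in either direction with isoginkgetin. With DMSO alone these shares were 5.95, 6.09, 9.06 and 4.61%. Of the exon probe sets 1.45, 2.32, 1.03 and 0.553% lay so far apart with isoginkgetin, and 0.444, 0.578, 0.885 and 0.351% with DMSO alone. Of 913055 probe sets limma called 0 in either line, with 6729 in HCT116 and 3073 in the p53-null subline at an unadjusted p under 0.05, and 0 with the block, also without the arrays labelled HCT116 replicate 1. The level of each probe set relative to the exons of its gene, tested for 640738 probe sets, also gave 0 calls in either line, with 9836 and 4981 at an unadjusted p under 0.05. In simulated data for the p53-null subline the tests of that line recovered 0% of 8-fold changes without the block, and 21.2% of single probe sets and 6.06% of relative levels with it, so that they would miss most such changes of single junctions or exons there. The test within the 4 sets, a test added after the data were seen, called 2 probe sets, with 81527 at an unadjusted p under 0.05. These were a junction of SLC39A10 (−1.70 log2, SE 0.05, limma adjusted p = 0.0030) and a junction of MT1IP, an uncertain metallothionein pseudogene (1.41, SE 0.06, 0.019), both chosen after their values were seen. Relative to the exons of the gene it called 0, with 51615 at an unadjusted p under 0.05. Both tests called 1 probe set without the arrays labelled HCT116 replicate 1, a junction of DBF4, a regulator of the kinase CDC7 that was chosen after its values were seen. Its relative level changed by −2.98, −3.12 and −3.26 log2 in the 3 sets (limma −3.12 log2, SE 0.10, adjusted p = 0.028) and by −1.81 in the arrays left out. DMSO against untreated gave 0 calls within the 4 sets (30722 probe sets and 23525 relative levels at an unadjusted p under 0.05), but also 1 call each in the 3 sets.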

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

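The tests of why the arrays labelled HCT116 replicate 1 stand apart, of a missing or prior response in them, of other splits of the vehicle arrays and for single probe sets, and of the difference on exon means were chosen after the results were seen; the tests on equal gene-level values, on the top of the scale and on the splits of the drug arrays were written before.

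The arrays labelled HCT116 replicate 1 lay far from the other 3 sets in all 3 treatments. A separate scaling of each set would keep the ranks of the gene-level rows. The highest Spearman correlation of this set with another was 0.869 over these rows, below the lowest one among the other sets (0.937), which argues against it. HCT116 RNA mixed with RNA of other cells is argued against as well, since the median of the 7 colon markers above 8 log2 in the other sets, of 14 measured, lay at −6.78 log2 relative to those sets, further down than a mixture with a sizeable share of HCT116 RNA would put it. RNA of other cells under this label stays open as a candidate explanation, because all 7 of these markers lay under 6 log2. No biological explanation was tested.

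Most gene-level values were exactly equal on the 3 arrays of a set, although drug effects were called from the exon probe sets. A gene-level summary that gave the arrays of a set 1 value may hide changes, and 9.25% of the called genes (42 of 454) had equal gene-level values in all 3 sets without HCT116 replicate 1, against 72.8% of all genes. Of these 454 called genes, 211 had equal gene-level values in 1 or more of the sets, although their exon means were called as changed. The share of 9.25% lies between the bounds set beforehand. It therefore does not decide how far the equal rows hide drug changes. If the RNA of the genes with equal values did not change, the spread of drug differences on exon probe sets would equal that of vehicle differences. The ratios of these spreads were 1.45, 1.00 and 1.17, of which the lowest leaves open whether the drug changed these genes. Exact equality is a separate point. Exon means differed even between the DMSO and untreated arrays of these 3 sets, with an SD over all genes of 0.067 to 0.103 log2. Together with the 211 called genes, this argues against unchanged RNA alone as the source of exactly equal values.

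The ATF4 list (adjusted p = 0.35 with an estimated correlation) and CHAC1, DDIT4 and SLC7A11 rose in 3 sets, and their values lay near 0 in the arrays labelled HCT116 replicate 1. An absent effect of isoginkgetin in these arrays is argued against by 28 genes that lay 2-fold apart from DMSO, compared with 0 between DMSO and untreated arrays. For most of the list, levels at the top of the scale are argued against, as 9.09% of it lay within 2 log2 of the highest gene (16.73 log2). The highest list member lay at 16.73 log2 as well. This share does not cover single members such as CHAC1, DDIT4 and SLC7A11. A list already high before the drug remains a candidate explanation: its DMSO level exceeded the other sets by 1.87 log2, at percentile 100 of random lists matched on level, but a difference between cells under this label, if there is one, would give the same value. The difference of this set from the others was tested gene by gene and is given under the other observations.

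Within the 4 sets, 1 of the 35 splits of the 8 arrays, the real one, gave 574 or more genes, and the highest other gave 0. The replicate numbers are taken to pair the arrays. The 8 splits that part all pairs, as the real one does, are too few for a share under 0.05. The highest other among them gave 0. The other splits join arrays of a pair. For the 3 sets the real split gave 476 genes and the highest other 0 (1 of 10 splits gave as many), but 10 splits are too few. For DMSO against untreated, 35 of 35 splits gave at least as many genes as the real one, which gave 0. A real count of 0 fixes this outcome, so that it says nothing about chance. The highest other gave 162, in the split that set the lines apart. The set blocks take up the difference of levels between the lines. The 162 calls thus compare the isoginkgetin responses of the lines, with DMSO and untreated arrays together as control.

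For single probe sets within the 4 sets, 1 of 35 splits, the real one, gave 2 or more calls, and the highest other gave 0. The 8 splits that part all pairs are too few for a share under 0.05, and the highest other among them gave 0. In the 3 sets the real split gave 1 call and the highest other 0, for probe sets and relative levels and for the drug and the vehicle alike (1 of 10 splits gave as many each time), but 10 splits are too few. Where the real count within the 4 sets was 0, for relative levels with the drug and for both levels with the vehicle, 35 of 35 splits gave as many, which says nothing about chance. The highest other gave 1, 0 and 1 there, for relative levels with the drug, probe sets with the vehicle and relative levels with the vehicle.

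Lists whose isoginkgetin responses differed between the lines on the gene-level rows were set aside for a closer look. The arrays labelled HCT116 replicate 1 enter these values, and most rows were exactly equal between isoginkgetin and DMSO within a set. Given as the mean of p53-null minus HCT116, they were the aminoacyl-tRNA synthetases (0.08 log2, camera adjusted p = 0.045, but adjusted p = 0.88 with an estimated correlation), the ER unfolded protein response (0.10, adjusted p = 1.1e-06, but adjusted p = 0.58 with an estimated correlation) and the immediate early genes (0.13, adjusted p = 8.1e-06, but adjusted p = 0.33 with an estimated correlation). Further ones were hypoxia and glycolysis (0.06, adjusted p = 0.0021, but adjusted p = 0.73 with an estimated correlation), DNA replication (0.09, adjusted p = 8.1e-06, but adjusted p = 0.71 with an estimated correlation) and ribosome biogenesis (0.13, adjusted p = 1.7e-10, but adjusted p = 0.33 with an estimated correlation). The metallothioneins differed by −0.20 log2 (adjusted p = 0.0088, but adjusted p = 0.58 with an estimated correlation). On the exon means, list medians are given for HCT116 replicate 1 and 2, then p53-null replicate 1 and 2. They overlapped between the lines for synthetases (0.01, 0.16, 0.24, 0.12), immediate early genes (−0.15, 0.02, 0, 0.02) and hypoxia (−0.02, −0.02, 0.03, −0.13). Those of the ER, DNA replication, ribosome biogenesis and metallothionein lists did not overlap.

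Among the genes that the naming rule picks, both sets of one line moved one way and both sets of the other line the opposite way in 21. In the limma test of the difference over all sets 0 of them passed (adjusted p of 0.12 to 0.47), and 16 without the arrays labelled HCT116 replicate 1, with a lone HCT116 set. The genes were chosen for this pattern, so that neither count tests it. Higher in the p53-null response were NPM3 (0.75 log2), HK2 (0.73), TSR3 (0.70), SLC2A1 (0.66), PRPF4 (0.62), BYSL (0.47), NOLC1 (0.46), XPC (0.42), POLR1B (0.37), RRN3 (0.30), SRSF6 (0.29), CCNE1 (0.29), HSPA6 (0.26), RRP9 (0.25), WDR43 (0.24) and HERC5 (0.22). Lower were NPW (−0.84), NUPR1 (−0.72), ATP5F1C (−0.44), H1-4 (−0.37) and HSPB1 (−0.22).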

How the results depend on the processing

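With isoginkgetin in HCT116, where the designed test called 0 rows, 19 passed at 2-fold and an unadjusted p, 175 with the replicate block, 698 with the block on exon means, 2580 with that fit without the arrays labelled HCT116 replicate 1, and 485 with an intensity trend. In the p53-null subline the same settings gave 11, 29, 75, 447 and 3. The difference of the responses went from 0 to 3 at 2-fold and an unadjusted p, 122 with the block and 1104 on exon means without the arrays labelled HCT116 replicate 1. The vehicle in HCT116 went from 0 to 8 with the block, and in the p53-null subline to 4 with the block and 4 at 2-fold and an unadjusted p. Leaving out single arrays kept all these counts at 0.

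The 6 calls between the lines in DMSO became 388 with quantile scaling (233 higher and 155 lower, against 1 and 5), 157 with centred arrays, 880 with only the groups compared, 1411 at 2-fold and an unadjusted p, 0 with the plain unpaired test, 59936 with the replicate block, 134 with untreated arrays added, 702 without the arrays labelled HCT116 replicate 1, 3 with exon means and a random block, and 142 with exon means without that set. Leaving out single arrays gave 4 to 5.

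Within the 4 sets, the 574 calls (207 higher and 367 lower) became 20 with the median of exon probe sets, 2014 with DMSO and untreated arrays as control, 9 at 2-fold, 0 without the block and 1 to 476 with 1 set left out. Quantile scaling gave 292 higher and 274 lower.

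The replicate block, read from the pairing of replicate numbers, also moved the junction value from 0.00388 to −0.0011, and left-out arrays moved it from −0.0215 to 0.0288. It changed no call for single probe sets or their relative levels within a line.

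The number of lists, 13 in HCT116, became 1 with an estimated correlation, 9 with the block, 6 with rows above the median level, and 13 to 24 with an array left out. In the p53-null subline 9 became 4 with an estimated correlation, 7 with the block, 4 with quantile scaling, and 6 to 14 with arrays left out. For the difference 7 became 0 with an estimated correlation, 10 with the block, 11 with quantile scaling and 5 to 23 with arrays left out. Between the lines 8 became 0 with an estimated correlation, 2 with the block, 15 without the arrays labelled HCT116 replicate 1 and 7 to 17 with an array left out. Within the 4 sets 10 became 0 with an estimated correlation and 7 to 9 with a set left out.

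Of 932 alternative values of named genes, 781 were the same, 84 weaker, 32 stronger and 35 moved. A gene called in neither fit counts as the same unless its sign turned. This holds for many values of CDKN1A, MDM2, ATF3, ATF4 and DDIT3, which had no call in the gene-level tests. Genes named only from the within-set tests of a single line do not enter. These counts therefore do not measure how stable the named responses were. The direction was not kept for every named gene, as that of SLC2A3 between the lines in DMSO turned over all arrays. Of the 59936 calls of the block between the lines, 38448 had a spread under 0.01. For all changed results the cause was not tested. The number of arrays limits the precision of all counts.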

Other observations

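The tests and values given here were all chosen after the results were seen. The isoginkgetin response of the arrays labelled HCT116 replicate 1 was compared with that of the other 3 sets by limma on exon means, with the lone set assumed to vary like the others. The test called 179 genes (83 higher and 96 lower, 2349 at an unadjusted p under 0.05). AVIL, an actin regulator, was higher by 2.11 log2 (adjusted p = 0.0026), with 2.24 in this set and 0.05 to 0.22 in the others. TXNIP, an inhibitor of thioredoxin, was higher by 1.1 log2 (adjusted p = 0.0039), FHDC1 by 1.09 (0.0030) and CD101 by 1.04 (0.0039). The metallothionein MT1M was higher by 0.96 log2 (adjusted p = 0.0089), and this value and that of the antisense gene PARD6G-AS1 (1.60, 0.0039) are uncertain. HELB, a DNA helicase, was lower by 0.98 log2 and IFIT3, an interferon-induced gene, by 0.98 (adjusted p = 0.0039 and 0.0050).

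EDA2R, a target of p53, lay at 10.34 log2 in the arrays labelled HCT116 replicate 1 and at 2.77 to 2.98 in the other sets. Between 678 and 699 of 22411 genes lay more than 16-fold apart between this set and another, compared with 11 to 21 among the other sets.

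Across 18587 genes, the responses of the 2 p53-null sets correlated at a Pearson r of 0.6, and that of HCT116 replicate 2 with them at 0.38 and 0.34. For the arrays labelled HCT116 replicate 1 the values were 0.3, 0.26 and 0.17, and for DMSO minus untreated 0.01 to 0.16. Genes are not independent replicates.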
